A study of Mus musculus with 16 samples.

How the data were processed

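RNA levels were measured on Affymetrix mouse arrays in mammary epithelial cells sorted from 4 female mice aged 10 weeks, 2 lacking Cpeb2 and 2 wild type, each of which gave 4 sorted populations and so 4 of the 16 arrays. The labels give Sox2-Cre +/+ for all 4 mice, so wild type means Cpeb2 +/+ with the Cre, and no group without the Cre was analysed here. Per the labels' protocols, 15 ng of total RNA was amplified by whole transcriptome amplification and 8 µg of cDNA was labelled with biotin. The values analysed are log2 expression values per probe set as deposited by the submitters, and RMA and limma are the tools in the submitters' processing notes, which give neither their role nor a version. The array background correction, any batch correction and any filter are not given in the sources used here. The table holds 45141 probe sets, with values from 3.40 to 13.60 and array medians from 6.35 to 6.40. Replicate arrays correlated across probe sets at r = 0.977 to 0.992. Precision is limited by the number of arrays, which is 2 per genotype and population.

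Probe sets were named through the annotation table supplied for the array. It gave 1 gene symbol for 28898 probe sets, several for 551 and none for 15588, and 104 probe sets were controls. The Entrez identifiers of 28689 named probe sets matched the mouse gene table of assembly GRCm38.p6, and 0 symbols changed. For each gene the probe set with the highest mean over all arrays was used, which gave 17097 genes, 7180 of them with more than 1 probe set. Among genes with several probe sets called in the mean knockout effect, 3 of 852 had another probe set called in the opposite direction, and 99 of 3772 did in the comparison of myoepithelial with luminal cells. Of the named genes, other probe sets are given for Cpeb2, Cpeb4, Epcam, Sdha and Tnfsf11 only. The lower quartile of all probe sets lay between 5.08 and 5.18 in the arrays. Where a gene named by size lay under it in every array of the dimmer side, or on average there, the text names it, and its difference is a lower bound in size. Genes under it in single arrays only are not all named. That was looked at after the data were seen.

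All 16 arrays entered one limma model (version 3.58.1, in R 4.3.3, with statmod 1.5.0) with a mean for each of the 8 groups of genotype and population. The mouse was a random block (duplicateCorrelation, consensus correlation 0.0383), and eBayes was run with a trend on mean expression, with 8 residual and 3.90 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Knockout was compared with wild type within each population and as the mean of the 4 within-population differences. An F test over 3 independent differences asked whether the knockout effect differed between populations. Populations were compared as the mean of both genotypes. Differences are log2, knockout minus wild type or the first named population minus the second, followed by the standard error of the fit.

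Gene lists were fixed before the data were examined, as were the comparisons, the naming rule and most alternatives. They held 472 genes, of which 422 were measured, in 27 lists, some of which shared genes, and 25 lists were tested. They covered the cell cycle, oxidative phosphorylation, cholesterol and fatty acid synthesis, hypoxia and glycolysis, the unfolded protein response, ribosomal proteins, the immediate early and dissociation stress response, the interferon response, NF-kB targets, the Notch and Wnt pathways, the estrogen response, the progesterone and RANKL axis, the poly(A) machinery, milk proteins, markers of hormone-sensing, alveolar, luminal and myoepithelial cells, and markers of leukocytes, endothelium, fibroblasts, adipocytes, pericytes and red cells. Lists were tested with limma's cameraPR at a preset correlation of 0.01 between genes, adjusted over the 25 lists, and again with camera at a correlation estimated for each list. The second test also had no mouse block, so the estimated correlation is not its only difference. Every list called in a knockout comparison lost its call in the second test. The adjusted p of that test, marked by its estimated correlation, is given beside each named list. With it, 3 lists stayed called for myoepithelial against luminal cells, 4 for non-clonogenic luminal cells against ductal progenitors, 2 for ductal against alveolar progenitors and 4 for non-clonogenic luminal cells against alveolar progenitors.

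The text names the CPEB family, Tnfsf11 and the sort antigens. In each comparison it may name up to 10 genes with the largest rise and 10 with the largest fall among called genes whose replicates did not overlap and moved the same way in both parent pairs (for population comparisons, in all 4 mice). It may also name the 5 smallest p of the F test and up to 4 called members per list. Genes without an established symbol were counted but not named. The sort antigen Sca1 was not analysed here.

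Mouse 1 of each genotype came from one father and mother and mouse 2 of each from another pair, per the labels, so the replicate numbers pair mice across genotypes. Deviations of the paired arrays from their group means correlated across genes at 0.0737 in non-clonogenic luminal cells, -0.00688 in ductal progenitors, 0.0593 in alveolar progenitors and -0.0432 in myoepithelial cells. The fit with the parent pair as a block was an alternative. Other alternatives were no mouse term, the mouse as a fixed block, no trend, array weights, dim genes left out, centring, a second quantile normalization, the mean of all probe sets, no probe sets with the suffix _x_at, a fold threshold of 1.5, the 4 arrays of a population alone, the mean of each mouse's arrays, one genotype alone and each mouse left out. Leaving out each single array was added after the data were seen. Where a leave-out left 1 array in a group, that array was assumed to vary like the other groups.

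On simulated data with 200 of 17097 genes changed, the comparison in non-clonogenic luminal cells recovered 35.8% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 87.9% of those changed 4-fold, with 7 unchanged genes called. The mean knockout effect recovered 85.1%, 97.0% and 98.5%, with 18 unchanged genes called, and the comparison of non-clonogenic luminal cells with ductal progenitors recovered 62.7%, 83.6% and 100%, with 4 unchanged genes called. In the non-clonogenic luminal simulation, 0 of 100 random lists were called by cameraPR, and the 1 list raised 2-fold had an unadjusted p under 0.05. The noise was drawn for each gene independently, so this check says nothing about lists whose genes move together. Correlations estimated for the real lists reached 0.726. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.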

Results

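The data describe sorted epithelial cells of the mouse mammary gland with and without Cpeb2, a cytoplasmic polyadenylation element binding protein that attaches to 3′ untranslated regions of messenger RNAs and acts on their poly(A) tails and translation. There were 4 populations. Myoepithelial cells (Epcam low, CD49f high) are the contractile outer layer. The luminal cells (Epcam high, CD49f low) were split into non-clonogenic luminal cells (Sca1 positive, CD49b negative), ductal progenitors (Sca1 and CD49b positive) and alveolar progenitors (Sca1 negative, CD49b positive). Each population was taken from the same 4 mice, 2 knockout and 2 wild type, which gave 16 arrays in 8 groups of 2. The labels give Sox2-Cre for all 4 mice, so wild type here means Cpeb2 +/+ with the Cre. The study's title places the comparisons in a question about Cpeb2, the cytokine RANKL (Tnfsf11) and mammary development.

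Cpeb2 itself was lower in knockout than in wild type in the mean of the 4 populations, where it fell by 0.92 ± 0.21 log2 units (adjusted p = 0.0201). Within single populations its brightest probe set differed by -1.45 ± 0.41 in non-clonogenic luminal cells (adjusted p = 0.0933), -1.08 ± 0.41 in ductal progenitors (adjusted p = 0.113), -0.74 ± 0.41 in myoepithelial cells (adjusted p = 0.449) and -0.39 ± 0.41 in alveolar progenitors (adjusted p = 0.925), none past the threshold with 2 mice per genotype. In non-clonogenic luminal cells the wild-type arrays read 8.33 and 8.66, knockout mouse 1 read 6.42 and knockout mouse 2 read 7.67. The other probe sets of Cpeb2 showed mean differences of -0.33 ± 0.17 and -0.28 ± 0.17 (adjusted p = 0.25 and 0.32 over all probe sets). In the mean of both genotypes, which includes the knockout arrays, Cpeb2 RNA was 2.44 ± 0.28 higher in non-clonogenic luminal cells than in alveolar progenitors. It was 2.08 ± 0.28 higher in ductal than in alveolar progenitors. In wild-type mice 1 and 2 alone, the same probe set read 7.88 and 8.00 in ductal and 5.52 and 5.53 in alveolar progenitors. Tnfsf11 lay near the low end of the scale in every population, with values of 5.01 to 5.54 on its brightest probe set and a mean knockout difference of -0.06 ± 0.07. Its other probe set read 4.55 and 4.35 in wild-type mouse 1 in non-clonogenic luminal cells and ductal progenitors. In all other arrays it read 3.82 to 4.03, with a mean knockout difference of -0.09 ± 0.09. These values lie near or under the lower quartile of all probe sets, so a change in Tnfsf11 may not be seen. Where the probe sets of Cpeb2 lie relative to the deleted part is not given in the sources used here, so a probe set outside that part checks nothing about the genotype.

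**Figure D1:**
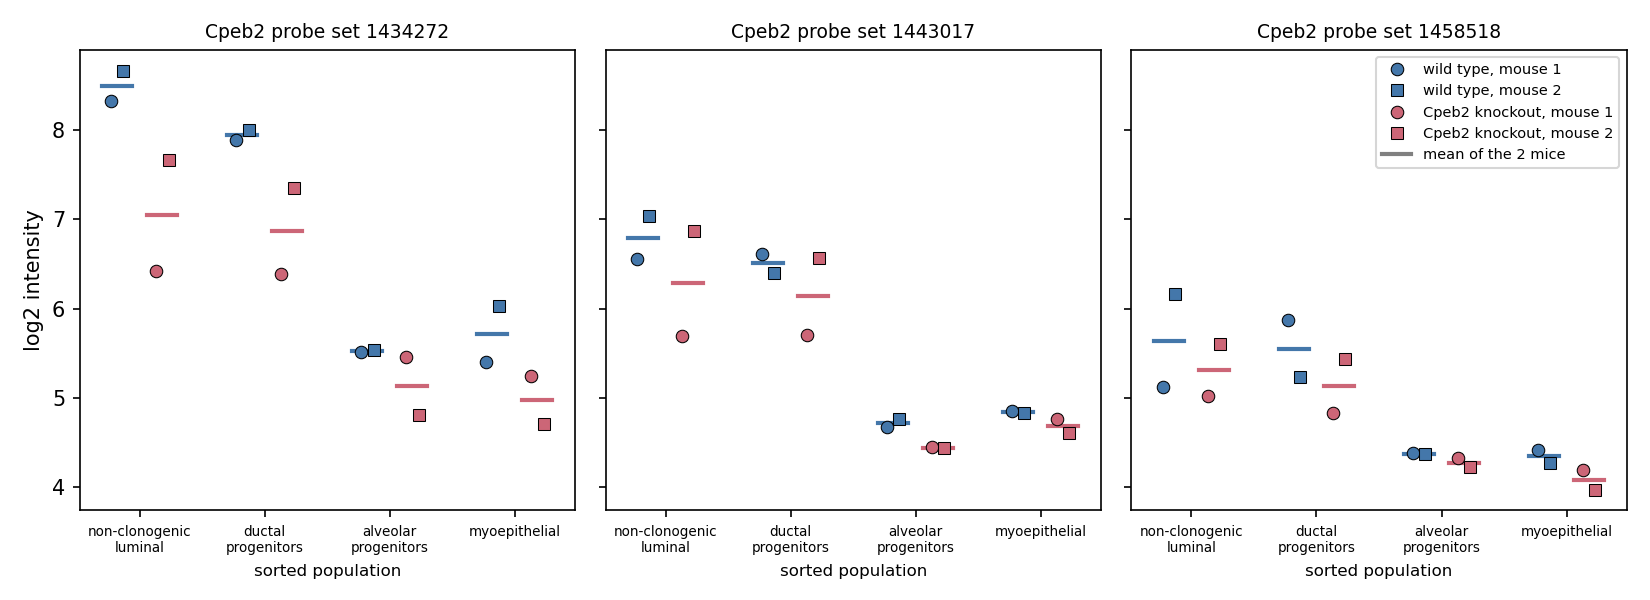
Log2 intensity (vertical axis) of the 3 Cpeb2 probe sets in each of the 16 arrays, by sorted population (horizontal axis), genotype (colour) and mouse (symbol), with lines at the mean of 2 mice. On the brightest probe set in non-clonogenic luminal cells, both knockout arrays (6.42 and 7.67) lie below both wild-type arrays (8.33 and 8.66), with knockout mouse 2 nearer to wild type. On the other probe sets knockout mouse 2 lies between the wild-type arrays in these cells.

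In non-clonogenic luminal cells, RNAs of mitosis and DNA replication were lower in the knockout. Pclaf, which binds the replication clamp PCNA, fell by 4.21 ± 0.65 log2 units (2 mice per genotype, adjusted p = 0.0107), and the thrombin receptor gene F2r fell by 4.04 ± 0.75 (adjusted p = 0.0249). The mitotic kinase gene Pbk (-3.71 ± 0.66), the kinetochore genes Zwilch (-3.59 ± 0.59) and Spc25 (-3.47 ± 0.67), and Nusap1 (-3.44), Racgap1 (-3.44), Ect2 (-3.37), Trip13 (-3.34) and Cep55 (-3.34), which act in spindle assembly, its checkpoint or cytokinesis, fell as well. Among the rises were Gatb, a mitochondrial tRNA amidotransferase subunit (2.05 ± 0.42), the stress-response gene Gadd45g (1.93 ± 0.41), the rhomboid protease gene Rhbdl2 (1.80 ± 0.34), the cadherin gene Cdh13 (1.79 ± 0.30), Fxyd2 (1.76), Ly6d (1.67), the tRNA-modifying enzyme gene Dus2 (1.67), Mal (1.65), Ahcyl2 (1.47) and the sulfotransferase gene Chst8 (1.46). F2r, Ect2 and Cep55 read under the lower quartile of all probe sets in both knockout arrays, and Pbk and Nusap1 in 1 of them and on average, so these differences are bounds and the order is not exact.

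Of the 35 measured cell cycle genes in these cells, 35 had a lower mean in knockout and 14 were called (34 adjusted over the list alone), including Ccna2 (-3.33), Mcm5 (-3.26) and Top2a (-3.14). The list's median was -2.15, with a camera adjusted p of 5.57e-34 at the preset correlation and an adjusted p of 0.645 with an estimated correlation. Hormone-sensing luminal markers rose as a list (median 0.59, adjusted p = 0.0369, and adjusted p = 0.659 with an estimated correlation). Called among 15 were Fxyd2 and Ly6d. Genes of oxidative phosphorylation fell as a list (median -0.23, adjusted p = 0.00768, and adjusted p = 0.659 with an estimated correlation), with 0 of 23 members called by limma, while 17 had a lower mean. No member was called by limma in the 4 lists that follow. Immediate early and dissociation stress genes were higher (20 of 25 on average, median 0.30, adjusted p = 0.0369, and adjusted p = 0.659 with an estimated correlation), with medians from -0.11 to 0.52 over leave-outs. Hypoxia and glycolysis genes were higher (16 of 17 on average, median 0.46, adjusted p = 0.0369, and adjusted p = 0.670 with an estimated correlation), with medians from -0.08 to 0.98. Unfolded protein response genes were higher (17 of 20 on average, median 0.39, adjusted p = 0.0369, and adjusted p = 0.659 with an estimated correlation). Interferon response genes were lower (18 of 21 on average, median -0.36, adjusted p = 0.0470, and adjusted p = 0.670 with an estimated correlation). These 4 lists kept their calls in 15, 14, 15 and 10 of 20 leave-outs. In all, 353 of 17097 genes were called, 295 lower and 58 higher in knockout, and 230 of them differed by 2-fold or more. The count was 36 without knockout mouse 1 and 0 without knockout mouse 2 (1376 genes at an unadjusted p under 0.05, limma). It was 906 without wild-type mouse 2, 45 without the wild-type array of mouse 1, 22 without the knockout array of mouse 2 and 86 from these 4 arrays alone. The hormone-sensing list lost its call without knockout mouse 2 or either of those arrays (median 0.18 to 0.69 over leave-outs). The oxidative phosphorylation list lost it without knockout mouse 1, its array of this population, or either wild-type mouse (median -0.29 to -0.16). Signal of the 3′ probe set less that of the middle one, a sign of RNA integrity, was 0.25 and 0.39 for Actb in wild-type mice 1 and 2 against 0.22 and 0.03 in knockout, which parts the genotypes. For Gapdh it overlapped (0.42 and 0.21 against 0.43 and -0.03).

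In ductal progenitors many of the same division genes fell in knockout, and several luminal genes rose. F2r fell by 4.37 ± 0.75 log2 units (2 mice per genotype, adjusted p = 0.0106) and Pclaf by 3.90 ± 0.65, as did Cep55 (-3.83 ± 0.70), Zwilch (-3.76 ± 0.59) and Nusap1 (-3.73 ± 0.74). Top2a, the topoisomerase of dividing cells (-3.69), Ect2 (-3.61), the cyclin gene Ccna2 (-3.56), the centromere gene Cenpf (-3.55) and Racgap1 (-3.54) followed. Slc5a5, the sodium iodide symporter, rose by 2.81 ± 0.63 (adjusted p = 0.0269), Gadd45g by 2.57 ± 0.41, Rhbdl2 by 2.50 ± 0.34, Gatb by 2.45 ± 0.42, Fxyd2 by 2.29 ± 0.40 and Ly6d by 2.07 ± 0.31, with Fbrsl1 (1.97), Dkkl1 (1.91), the sphingosine kinase gene Sphk1 (1.91) and Dmbt1 (1.89) also higher. F2r, Cep55, Nusap1 and Ect2 read under the lower quartile in both knockout arrays, so their ranks are not exact.

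The cell cycle list in ductal progenitors had 22 of 35 genes called lower (31 adjusted over the list alone) and a median of -2.29 (adjusted p = 5.97e-27, and adjusted p = 0.672 with an estimated correlation). Hormone-sensing markers rose (median 0.68, adjusted p = 0.0168, and adjusted p = 0.672 with an estimated correlation). Called among 15 were Fxyd2, Ly6d, the estrogen receptor gene Esr1 (0.91) and Prom1 (0.86). Prom1 is one of the 200 measured genes nearest to Cpeb2, so alleles linked to the deletion are not excluded for it. Interferon response genes fell (median -0.59, adjusted p = 0.00204, and adjusted p = 0.805 with an estimated correlation). Called among 21 were Ifit1 (-2.08) and Irgm1 (-1.24). Of 25 genes of the poly(A) machinery 5 were called lower (6 adjusted over the list alone): the deadenylase genes Cnot7 (-0.82), Cnot6 (-0.75) and Parn (-0.71), the poly(A) polymerase gene Tent4b (-0.77) and the poly(A) binding protein gene Pabpc1 (-0.53). That list's median was -0.15 (adjusted p = 0.0168, and adjusted p = 0.672 with an estimated correlation). The alveolar list did not pass (median -0.23, adjusted p = 0.0513, and adjusted p = 0.738 with an estimated correlation). Of its 17 members 9 had a lower and 8 a higher mean. Kit (-1.76), Elf5 (-1.61), Rspo1 (-1.20) and Tfap2c (-1.07) were called lower, and adjusted over the list alone 5 were lower and 3 higher. On an axis of 200 genes from the non-clonogenic luminal mean (0) to the alveolar mean (1) of the same genotype, the ductal arrays of wild-type mice 1 and 2 lay at 0.470 and 0.335, and those of knockout mice 1 and 2 at 0.229 and 0.263. The leukocyte list was also called (median 0.16, adjusted p = 0.0498, and adjusted p = 0.672 with an estimated correlation). Called among 21 was Csf1r (0.49).

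Ductal progenitors had 1272 called genes, 744 lower and 528 higher, 605 of them by 2-fold or more. The count was 37 without knockout mouse 1, 17 without knockout mouse 2, 323 without wild-type mouse 1 and 3393 without wild-type mouse 2. Single arrays moved it to 47 (wild type, mouse 1), 2945 (wild type, mouse 2), 57 (knockout, mouse 1) and 283 (knockout, mouse 2), and these 4 arrays alone gave 69, of which 66 were lower. The 3′ less middle signal parted the genotypes in these arrays for both control genes. For Gapdh it was 0.60 and 0.39 in wild-type mice 1 and 2 against 0.15 and 0.12 in knockout, and for Actb 0.12 and 0.27 against 0.05 and 0.06. The interferon list lost its call without wild-type mouse 2 or its ductal array (median -1.09 to -0.23 over leave-outs), the hormone-sensing list without knockout mouse 2, its ductal array or that of wild-type mouse 2 (0.39 to 0.97). The poly(A) list lost it without either wild-type mouse or the ductal array of mouse 1 (-0.26 to -0.13), and the leukocyte list kept its call in 4 of 20 leave-outs (0.13 to 0.22).

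Several DNA replication genes fell in alveolar progenitors of knockout mice. Mcm5, a subunit of the replicative helicase, fell by 3.67 ± 0.47 log2 units (2 mice per genotype, adjusted p = 0.00442). Its partners Mcm2 (-2.60 ± 0.45) and Mcm3 (-2.52 ± 0.43) fell with it (adjusted p = 0.0238 for each). Zwilch (-2.96), Gins1 (-2.90), the methylation-maintenance gene Uhrf1 (-2.53), the primase gene Prim1 (-2.30) and the thymidylate synthase gene Tyms (-2.26) fell, as did C1qtnf1 (-2.48 ± 0.21) and Rspo1, a secreted enhancer of Wnt signalling (-2.45 ± 0.19, adjusted p = 0.000216). The neutrophil chemokine gene Cxcl2 rose by 2.33 ± 0.44, the apolipoprotein gene Apod by 2.30 ± 0.36, Prelp by 2.26 ± 0.42, the forkhead factor gene Foxi1 by 2.03 ± 0.22, Snorc by 1.93 and the potassium channel subunit gene Kcne3 by 1.92. Lrg1 (1.87), Papln (1.82), Arhgef6 (1.81) and the chloride channel family gene Clic6 (1.79) were higher too.

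Cell cycle genes in alveolar progenitors had a median of -1.29 (adjusted p = 2.08e-27, and adjusted p = 0.395 with an estimated correlation). Of 35 members 4 were called lower, namely Mcm5, Mcm2, Mcm3 and Tyms, and 23 were when adjusted over the list alone. The list's level in wild-type mouse 1 (-0.07) lay nearer to the knockout arrays (-0.54 and -0.82) than to wild-type mouse 2 (1.41), and the median difference ran from -2.19 without wild-type mouse 1 to -0.70 without wild-type mouse 2. Oxidative phosphorylation genes were lower as a list (median -0.31, adjusted p = 1.83e-07, and adjusted p = 0.395 with an estimated correlation). Of 23 members 23 were lower on average, and 3 were called when adjusted over the list alone. NF-kB targets rose (median 0.16, adjusted p = 0.000271, and adjusted p = 0.486 with an estimated correlation). Called among 20 were Cxcl2 and the granulocyte growth factor gene Csf3 (1.78), and the median ran from 0.08 to 0.25 over leave-outs. Immediate early and dissociation stress genes were higher as a list (median 0.33, adjusted p = 1.83e-07, and adjusted p = 0.395 with an estimated correlation). Of 25 members 24 were higher on average. Cholesterol and fatty acid synthesis genes were lower (14 of 16 on average, median -0.38, adjusted p = 0.00878, and adjusted p = 0.486 with an estimated correlation). They kept the call in 16 of 20 leave-outs, with medians from -0.62 to -0.13. The 3′ less middle signal of Gapdh parted the genotypes in these arrays too, the other way (0.14 and 0.18 in wild type, 0.49 and 0.23 in knockout), and that of Actb overlapped (-0.04 and 0.03 against 0.04 and -0.02). In all 106 genes were called, 46 higher and 60 lower, 81 of them by 2-fold or more. The count was 3 without knockout mouse 1, 23 without knockout mouse 2, and 315 without wild-type mouse 1. Without single alveolar arrays it was 54 and 43 (wild type, mice 1 and 2) or 39 and 68 (knockout), and it was 389 with array weights. With the parent pair as a block, 8 lists were called in place of 5.

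In myoepithelial cells, Mcm5 and Mcm2 fell by 3.15 ± 0.47 and 3.13 ± 0.45 log2 units in knockout (2 mice per genotype, adjusted p = 0.0112 and 0.00846). The DNA ligase gene Lig1 (-2.45), the histone gene H2bc4 (-2.42), Adamts20 (-2.32), Tyms (-2.08), the monoamine oxidase gene Maob (-1.78), the glutathione peroxidase gene Gpx2 (-1.76 ± 0.17), Adamts18 (-1.73 ± 0.16) and Atad5, which unloads PCNA (-1.70), fell as well. Cxcl2 rose by 2.32 ± 0.44, the transketolase-like gene Tktl1 by 2.18 ± 0.40, the aggrecan-cleaving protease gene Adamts5 by 1.68 ± 0.35, the growth factor gene Fgf2 by 1.65 ± 0.32, and Slc2a13 (1.52), Olfm2 (1.51 ± 0.15), the NADPH oxidase gene Nox4 (1.42), Tmem45a (1.42), Glis3 (1.38) and Nbl1 (1.36) were higher. Mcm2 read under the lower quartile in both knockout arrays, and Atad5 in 1 of them and on average, so these differences are bounds.

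Oxidative phosphorylation genes in myoepithelial cells fell (median -0.47, adjusted p = 5.61e-13, and adjusted p = 0.269 with an estimated correlation). Called among 23 were Ndufv1 (-0.90), Cox7a2 (-0.60) and Sdha (-0.80 ± 0.15), and 15 members were when adjusted over the list alone. The other probe sets of Sdha differed by -0.21 ± 0.12, 0.13 ± 0.12 and 0.54 ± 0.20 and were not called, so its fall rests on 1 of 4. The cell cycle list fell too (median -1.20, adjusted p = 2.01e-11, and adjusted p = 0.337 with an estimated correlation). Called among 35 were Mcm5, Mcm2 and Tyms, and 8 members were when adjusted over the list alone. Wild-type mouse 1 (-0.45) again lay between the knockout arrays (-0.94 and -0.96) and wild-type mouse 2 (0.83), and the median difference ran from -1.83 without the array of wild-type mouse 1 to -0.38 without that of wild-type mouse 2. The oxidative phosphorylation median ran from -0.69 without wild-type mouse 1 to -0.28 without wild-type mouse 2. Cholesterol and fatty acid synthesis genes were lower as a list (median -0.56, adjusted p = 0.000101, and adjusted p = 0.269 with an estimated correlation). Of 16 members 15 were lower on average. Interferon response genes were lower (20 of 21 on average, median -0.44, adjusted p = 0.0196, and adjusted p = 0.563 with an estimated correlation). Unfolded protein response genes were higher (18 of 20 on average, median 0.38, adjusted p = 0.000183, and adjusted p = 0.347 with an estimated correlation). Both kept their calls in 16 of 20 leave-outs, with medians from -0.86 to -0.06 for interferon response and from 0.05 to 0.63 for the unfolded protein response. NF-kB targets rose (median 0.44, adjusted p = 1.28e-06, and adjusted p = 0.269 with an estimated correlation). Called among 20 was Cxcl2. Markers of other cell types were higher in the same knockout arrays, first those of endothelium (median 0.56, adjusted p = 6.43e-08, and adjusted p = 0.269 with an estimated correlation). Called among 14 was the VEGF receptor gene Kdr (0.61). Their level was 1.10 in the array of knockout mouse 2, against 0.36 in knockout mouse 1 and 0.20 and 0.18 in wild-type mice 1 and 2, and the median difference ran from 0.14 without the array of knockout mouse 2 to 0.83 without knockout mouse 1. Luminal keratin and junction markers were higher as well (median 0.34, adjusted p = 0.00979, and adjusted p = 0.316 with an estimated correlation), with 10 of 14 higher on average. Their level was -1.67 and -2.30 in knockout mice 1 and 2 and -2.76 and -2.14 in wild-type mice 1 and 2. That list lost its call without mouse 1 of either genotype or its myoepithelial array (median 0.14 to 0.51 over leave-outs).

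Myoepithelial cells had 173 called genes, 97 lower and 76 higher, 94 of them by 2-fold or more. The count was 13 without knockout mouse 1, 17 without knockout mouse 2, 1391 without wild-type mouse 1 and 59 without wild-type mouse 2. Without single myoepithelial arrays it was 1211 (wild type, mouse 1), 80 (wild type, mouse 2), 78 (knockout, mouse 1) and 84 (knockout, mouse 2). It was 50 with array weights, 102 without dim genes (34 higher and 68 lower) and 0 from the 4 myoepithelial arrays alone with limma (1550 genes at an unadjusted p under 0.05). The cholesterol list lost its call without wild-type mouse 1 or its myoepithelial array (median -0.85 to -0.31 over leave-outs).

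**Figure D2:**
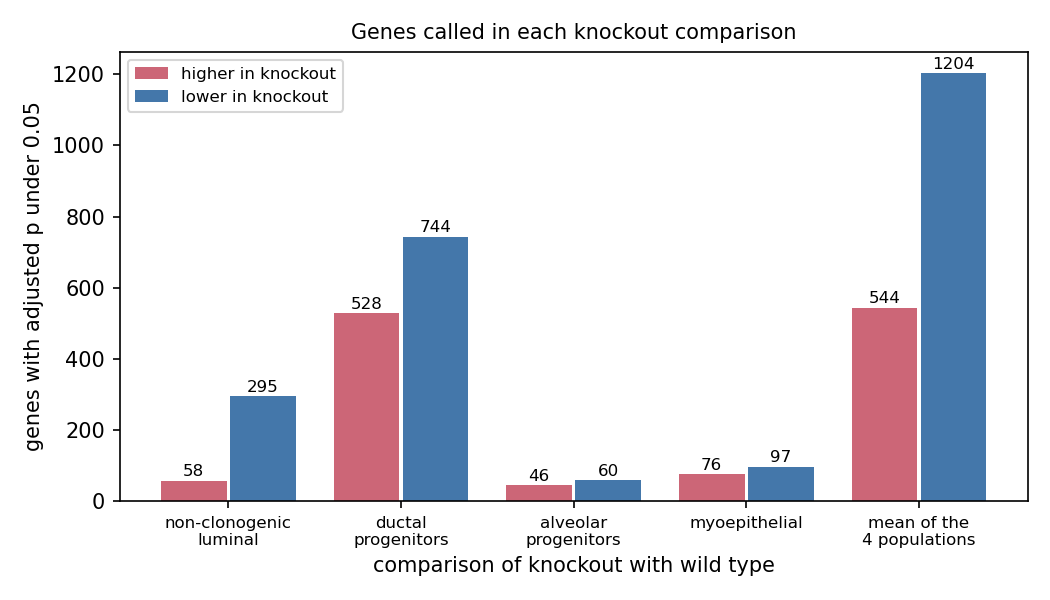
Number of genes with an adjusted p under 0.05 (vertical axis) that were higher or lower in knockout, for each sorted population and for the mean of the 4 populations (horizontal axis). Ductal progenitors have 528 higher and 744 lower genes, against 46 and 60 in alveolar progenitors.

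Over the mean of the 4 populations, replication and mitosis genes fell in knockout. The standard errors and p-values of this mean take the arrays of a mouse as nearly independent (consensus correlation 0.0383). Between non-clonogenic luminal and ductal arrays, differences between replicate mice correlated across genes at 0.554, so the errors and p-values may be too small. From the mean of each mouse's arrays, the smallest adjusted p of any gene was 0.000918 (limma). Mcm5 fell by 3.30 ± 0.25 log2 units (4 mice, adjusted p = 0.000112). Next were Pclaf (-3.26 ± 0.34), Zwilch (-3.22 ± 0.31), Pbk (-2.86), Ccna2 (-2.82), Racgap1 (-2.80), Cep55 (-2.72), Top2a (-2.71), Trip13 (-2.68) and the proliferation marker gene Mki67 (-2.68). Cep55 read under the lower quartile in all 8 knockout arrays and Pbk in 5 of 8 and on average, so these sizes are bounds and the order is not exact. Slc5a5 rose by 1.58 ± 0.33, Ido1, which starts tryptophan breakdown, by 1.37 ± 0.24, Papln by 1.33 ± 0.17 and Fxyd2 by 1.30 ± 0.21, with Dmbt1 (1.23), Sphk1 (1.18), Gadd45g (1.17), the aquaporin gene Aqp3 (1.14), the tissue factor gene F3 (1.09) and Ly6d (1.05) also higher. Atad5, Lig1, Mcm2, Mcm5 and Tyms were called lower in each of the 4 populations taken singly, and 0 genes were called higher in all 4 by limma.

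The cell cycle list had 32 of 35 genes called lower in this mean (35 adjusted over the list alone), with a median of -1.73 (adjusted p = 7.44e-51, and adjusted p = 0.395 with an estimated correlation). Its call held in each of the 20 leave-outs of a mouse or an array, with medians from -2.06 to -1.47. Oxidative phosphorylation genes fell (median -0.29, adjusted p = 1.34e-09, and adjusted p = 0.395 with an estimated correlation). Of 23 members 9 were called, among them Ndufb8 (-0.59) and Atp5o (-0.45). Cholesterol and fatty acid synthesis genes fell (median -0.38, adjusted p = 0.00196, and adjusted p = 0.418 with an estimated correlation). Called among 16 were Dhcr7 (-1.02) and Fdps (-0.70). Interferon response genes fell (median -0.47, adjusted p = 0.000409, and adjusted p = 0.457 with an estimated correlation). Called among 21 were Ifit1 (-0.95), Gbp2 (-0.69) and Irgm1 (-0.63). Hormone-sensing markers rose (median 0.47, adjusted p = 0.000923, and adjusted p = 0.418 with an estimated correlation). Called among 15 were Fxyd2, Ly6d, Esr1 (0.74) and Prom1 (0.63), which is near Cpeb2 as said above, and the median ran from 0.27 to 0.67 over leave-outs. Immediate early and dissociation stress genes rose (median 0.24, adjusted p = 0.00137, and adjusted p = 0.457 with an estimated correlation). Of 25 members 5 were called, among them Socs3 (0.96), Klf4 (0.81), Junb (0.72) and Fosb (0.51). Unfolded protein response genes rose (median 0.30, adjusted p = 0.00151, and adjusted p = 0.457 with an estimated correlation). Called among 20 were Ppp1r15a (0.56) and the chaperone gene Hspa5 (0.30). NF-kB targets were higher (5 of 20 called, median 0.23, adjusted p = 0.00871, and adjusted p = 0.457 with an estimated correlation) and kept the call in 16 of 20 leave-outs. Luminal keratin and junction markers were higher (2 of 14 called, median 0.16, adjusted p = 0.0367, and adjusted p = 0.457 with an estimated correlation) and kept it in 10 of 20.

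The mean effect called 1748 genes, 1204 lower and 544 higher, 210 of them by 2-fold or more. The count was 3431 with the parent pair as a block (1442 higher and 1989 lower), 492 from the mean of each mouse's arrays (480 shared with the 1748, and 440 lower), 696 at 1.5-fold or more, 645 without knockout mouse 1 and 279 without knockout mouse 2. It was 1023, 1010 and 1157 without the wild-type non-clonogenic array of mouse 1, the wild-type alveolar array of mouse 2 or the knockout myoepithelial array of mouse 2. The cholesterol list lost its call without knockout mouse 1 or wild-type mouse 1 (median -0.49 to -0.15 over leave-outs), the interferon list without knockout mouse 1 or wild-type mouse 2 (-0.91 to -0.11), the stress list without knockout mouse 1 (0.08 to 0.32) and the unfolded protein list without knockout mouse 2 or wild-type mouse 1 (0.08 to 0.49).

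**Figure D3:**
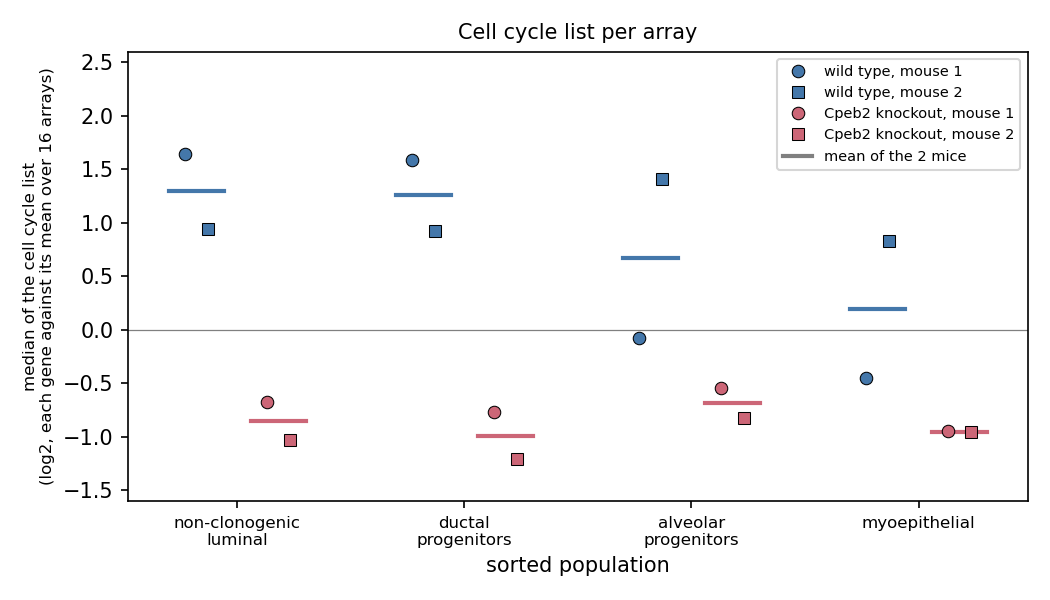
Median of the 35 measured cell cycle genes in each of the 16 arrays (vertical axis, log2, each gene against its mean over all arrays), by sorted population (horizontal axis), genotype and mouse, with lines at the mean of 2 mice. In non-clonogenic luminal cells wild-type mice lie at 1.65 and 0.94 and knockout mice at -0.67 and -1.03, while in alveolar progenitors wild-type mouse 1 (-0.07) lies close to the knockout arrays (-0.54 and -0.82).

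Genes lowered in non-clonogenic luminal cells and in ductal progenitors overlapped in 221, against 12.8 for independent lists of that length, and genes raised overlapped in 38, against 1.79. The same mice gave both populations, so part of that excess may come from the mice. Knockout effects in these populations correlated across genes at r = 0.835, where differences between replicate mice of one genotype, which hold no knockout effect, gave 0.554. These r values do not give the part due to the mice. On the same scale the covariance was 0.171 for knockout effects and 0.0330 from replicates, and 0.0456 and 0.0150 for alveolar with myoepithelial cells. These comparisons were chosen after the data were seen, and genes are not independent replicates. For alveolar with myoepithelial cells r was 0.426 against 0.307 from replicates, and for non-clonogenic luminal with alveolar cells 0.397 against 0.161. Ductal with alveolar cells gave 0.324 against 0.0547, non-clonogenic luminal with myoepithelial cells 0.316 against -0.0373, and ductal with myoepithelial cells 0.183 against -0.0342. The F test called 114 genes whose knockout effect differed between the 4 populations. Lcn2, the iron-siderophore binding lipocalin, had effects of -2.46 in non-clonogenic luminal cells and -0.23, 0.24 and 0.29 in ductal, alveolar and myoepithelial cells (adjusted p = 0.00209). Cd1d1, a lipid antigen presenting molecule, had -2.38, -2.05, 0.39 and 0.02 in the same order (adjusted p = 0.00226). Muc15, a membrane mucin, had -3.05 in ductal progenitors and -0.06, -0.59 and -0.45 in non-clonogenic, alveolar and myoepithelial cells (adjusted p = 0.00474). Clic6 had 1.79 in alveolar progenitors and -0.45, 0.37 and 0.12 in non-clonogenic, ductal and myoepithelial cells (adjusted p = 0.00474), and Rspo1 had -2.45 there, with -1.20 in ductal progenitors and 0.12 and -0.14 in non-clonogenic and myoepithelial cells (adjusted p = 0.00526). Muc15 and Rspo1 read under the lower quartile in all non-clonogenic and myoepithelial arrays, where a fall cannot be seen. In ductal progenitors Rspo1 read 5.64 in wild type and 4.44 in knockout, so its smaller fall there is a bound too, while Muc15 in alveolar cells (10.06 and 9.48) is not so limited. Both genes read higher in alveolar than in non-clonogenic wild-type cells (10.06 against 4.36 for Muc15, 7.65 against 4.34 for Rspo1). Wild-type ductal arrays lay nearer to the alveolar mean than knockout ones. For these genes that shift cannot be told apart from a knockout effect in ductal progenitors. Between ductal and non-clonogenic luminal cells alone, the effect differed in 2 genes. Without a mouse the count of 114 became 13 (knockout 1), 1 (knockout 2) or 1047 (wild type 2), and without an array it ran from 28 (knockout ductal, mouse 1) to 656 (wild-type ductal, mouse 2).

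Myoepithelial cells differed from the luminal populations by the contractile and basal genes that define them. Igfbp3 was 6.98 ± 0.13 log2 units higher (4 mice), the myosin kinase gene Mylk 6.80 ± 0.08, Scn7a 6.22 ± 0.22, smooth muscle myosin Myh11 6.05 ± 0.10 and Moxd1 5.98 ± 0.10, with Trp63 (5.86), keratin gene Krt14 (5.84), smooth muscle actin gene Actg2 (5.72), Krt5 (5.50) and Col17a1 (5.47) also higher. Smim22 (-6.00 ± 0.13), Bex1 (-4.94), the claudin genes Cldn7 (-4.91) and Cldn3 (-4.76), Tlcd4 (-4.83), Basp1 (-4.74), Mal2 (-4.70), Bik (-4.56), Cxcl15 (-4.53) and H2-Q1 (-4.44) were lower. Moxd1, Actg2, Bik and H2-Q1 read under the lower quartile in every array of their dimmer side. Igfbp3 did in 10 of 12, Bex1 and Tlcd4 in 3 of 4, and each on average, so all of these differences are bounds and the order is not exact. Of the sort antigens, Epcam was lower in myoepithelial cells (-1.10 ± 0.05) and Itga6, which encodes CD49f, was higher (adjusted p = 1.84e-05).

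All 17 measured myoepithelial markers were called higher (median 4.87, adjusted p = 9.26e-181, and adjusted p = 0.000124 with an estimated correlation). All 14 luminal keratin and junction markers were called lower (median -3.13, adjusted p = 2.24e-26, and adjusted p = 0.0195 with an estimated correlation). These marker lists restate the sort. Hormone-sensing markers were lower (10 of 15 called, median -3.01, adjusted p = 6.96e-10, and adjusted p = 0.0508 with an estimated correlation). Wnt pathway genes were higher (median 0.44, adjusted p = 1.75e-05, and adjusted p = 0.0439 with an estimated correlation). Of 21 members 12 were called higher and 3 lower, among them the stem cell receptor gene Lgr5 (4.85), Wnt10a (4.56), Fzd7 (3.16) and Lgr4 (2.92). Oxidative phosphorylation genes were lower (median -0.54, adjusted p = 0.000402, and adjusted p = 0.363 with an estimated correlation), with 18 of 23 called. Hypoxia and glycolysis genes were higher (median 0.81, adjusted p = 0.0398, and adjusted p = 0.575 with an estimated correlation). Of 17 members 13 were called, among them Car9 (3.60), Adm (2.25) and Egln3 (2.20). The progesterone and RANKL axis was called upward (adjusted p = 0.000168, and adjusted p = 0.928 with an estimated correlation) with a mean of 0.22 but a median of -0.82, since Fst (4.49) and Id4 (4.38) were higher and Cited1 (-3.88) lower. Endothelial markers were higher (median 0.65, adjusted p = 0.0458, and adjusted p = 0.481 with an estimated correlation). Cdh5 (1.93) and Kdr (1.16) were higher and Vwf (-1.38) lower, and the list lost its call with the parent pair as a block (adjusted p = 0.0564).

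The comparison called 8202 genes, 4025 higher and 4177 lower in myoepithelial cells, 2241 of them by 2-fold or more. The count was 5403 without knockout mouse 1, 5106 without knockout mouse 2 and 4160 at 1.5-fold or more. The hypoxia list lost its call without wild-type mouse 1, its alveolar array or any myoepithelial array but that of knockout mouse 1, the progesterone list without either wild-type mouse, while the endothelial list kept its call in 7 of 20 leave-outs.

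Several alveolar and milk genes were lower in non-clonogenic luminal cells than in ductal progenitors. Kappa-casein Csn3 was lower by -5.10 ± 0.18 log2 units (4 mice), transferrin Trf by -4.65 ± 0.34, Cyp1b1 by -4.62 ± 0.20, Wfdc18 by -4.15 ± 0.26 and Igfbp5 by -4.08 ± 0.19. Lactoferrin Ltf (-3.98), the retinal dehydrogenase gene Aldh1a3 (-3.74), the receptor kinase gene Kit (-3.65), Fabp5 (-3.51) and Dclk1 (-3.50) were lower as well. Sbp (0.84), Fgd4 (0.63), Angptl6 (0.51), the Wnt receptor gene Ror2 (0.47), Col8a2 (0.45), Smc2os (0.44) and Fbxo16 (0.33) were higher. Kit in non-clonogenic and Smc2os in ductal arrays read under the lower quartile throughout, and Cyp1b1, Igfbp5 and Dclk1 read near it in non-clonogenic arrays, so these differences are bounds. Alveolar markers fell as a list (10 of 17 called, median -1.31, adjusted p = 1.30e-119, and adjusted p = 0.000347 with an estimated correlation). So did milk protein genes (5 of 16 called, median -0.28, adjusted p = 1.48e-39, and adjusted p = 0.00289 with an estimated correlation). Fibroblast markers were lower in non-clonogenic cells too (0 of 13 called by limma, 12 lower on average, median -0.52, adjusted p = 0.000315, and adjusted p = 0.0320 with an estimated correlation). Immediate early and dissociation stress genes were lower (2 of 25 called, median -0.17, adjusted p = 4.88e-06, and adjusted p = 0.154 with an estimated correlation). So was the progesterone and RANKL axis (1 of 15 called, median -0.10, adjusted p = 0.000867, and adjusted p = 0.0334 with an estimated correlation). Its called member was Elf5, which, like its member Rspo1, is also in the alveolar list, so the calls of these lists are not independent. The other 7 called lists kept their calls in 8 to 16 of 20 leave-outs. Over leave-outs the fibroblast median ran from -0.75 to -0.17, the latter without the ductal array of wild-type mouse 1, and the milk median from -0.39 to -0.13. Itga2, which encodes the sort antigen CD49b, differed by -0.81 ± 0.17 (adjusted p = 0.0523). The test called 136 genes, 129 lower and 7 higher in non-clonogenic cells and 103 by 2-fold or more. The count was 50 without knockout mouse 1, 42 without knockout mouse 2, 281 without wild-type mouse 2, 263 without its ductal array and 40 in knockout mice alone.

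Ductal progenitors carried more RNA of hormone-sensing genes than alveolar progenitors. Wnt5a was 5.01 ± 0.27 log2 units higher (4 mice), Prss23 4.74 ± 0.23, Plac8 4.72 ± 0.27, the ceramide synthase gene Cers6 4.70 ± 0.28 and Cdo1 4.55 ± 0.28, followed by Fgg (4.50), Agtr1a (4.43), Ctse (4.40), Kif5c (4.39) and Snhg11 (4.38). Butyrophilin Btn1a1 (-3.06 ± 0.34), Ntn1 (-2.94), carbonic anhydrase Car2 (-2.92), Slc5a8 (-2.91), the proton pump gene Atp6v1b1 (-2.89), Wnt5b (-2.86), Cyp2d22 (-2.85), Muc15 (-2.85), Plscr2 (-2.83) and Slc1a1 (-2.83) were lower. Prss23 read under the lower quartile in every alveolar array. Of 15 hormone-sensing markers 13 were called higher and 1 lower (median 3.58, adjusted p = 2.99e-27, and adjusted p = 0.0163 with an estimated correlation), including Cited1 (4.16) and the progesterone receptor gene Pgr (4.11). Of 17 alveolar markers 13 were called lower and 1 higher (median -1.73, adjusted p = 3.43e-20, and adjusted p = 0.0163 with an estimated correlation), including Kit (-2.70), Sox10 (-2.53) and Elf5 (-2.51). The estrogen response list was higher (median 0.22, adjusted p = 0.00915, and adjusted p = 0.336 with an estimated correlation). Of 19 members 8 were called higher, among them Stc2 (3.39) and Esr1 (2.99), and 3 lower, with medians from 0.06 to 0.36 over leave-outs. Stc2, Esr1, Pgr, Greb1 and Cited1 are also in the hormone-sensing list, so the calls of these lists are not independent. Fibroblast markers were higher in ductal progenitors (median 0.85, adjusted p = 0.0332, and adjusted p = 0.149 with an estimated correlation). Of 13 members 5 were called, among them Col6a3 (3.58), Col3a1 (2.29) and Dcn (2.13). Immediate early and dissociation stress genes were lower in ductal progenitors (10 of 25 called lower and 1 higher, median -0.49, adjusted p = 0.00014, and adjusted p = 0.169 with an estimated correlation). Milk protein genes were lower too (7 of 16 called, median -0.84, adjusted p = 0.00069, and adjusted p = 0.0731 with an estimated correlation), with medians from -0.98 to -0.34 over leave-outs. Myoepithelial markers were lower (8 of 17 called lower and 1 higher, median -0.22, adjusted p = 0.0210, and adjusted p = 0.0731 with an estimated correlation) but lost the call without either wild-type mouse. NF-kB targets were lower (9 of 20 called, median -0.41, adjusted p = 0.0295, and adjusted p = 0.417 with an estimated correlation) and kept the call in 15 of 20 leave-outs. The test called 3759 genes, 1937 higher and 1822 lower, 1188 of them by 2-fold or more. The count was 1835 and 1748 without knockout mouse 1 or 2, 2154 in wild-type mice alone and 2446 at 1.5-fold or more, while the fibroblast list lost its call without knockout mouse 2, its ductal or alveolar array, or the ductal array of wild-type mouse 1 (median 0.28 to 1.41 over leave-outs).

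Non-clonogenic luminal cells and alveolar progenitors lay farther apart by count. Wnt5a was 5.05 ± 0.27 log2 units higher in non-clonogenic cells (4 mice), with Snhg11 (4.93), Plac8 (4.86), Prss23 (4.83), Cdo1 (4.75), Slc35f3 (4.75), Cers6 (4.74), Fgg (4.67), Ctse (4.66) and Kif5c (4.60) next. Cyp1b1 (-6.65 ± 0.20), Kit (-6.35 ± 0.19), Csn3 (-6.33 ± 0.18), Igfbp5 (-6.15), Trf (-6.14), Dclk1 (-6.11), the tight junction gene Cldn1 (-6.01), Btn1a1 (-5.76), Aldh1a3 (-5.73) and Wnt5b (-5.49) were lower. Kit and Wnt5b in every non-clonogenic array, and Prss23 in every alveolar one, read under the lower quartile. Cyp1b1, Igfbp5, Dclk1 and Cldn1 read near it in non-clonogenic cells, so all of these differences are bounds and their order is not exact. Of 17 alveolar markers 14 were called lower and 1 higher (median -3.35, adjusted p = 2.82e-53, and adjusted p = 0.00905 with an estimated correlation). Of 15 hormone-sensing markers 13 were called higher and 1 lower (median 3.69, adjusted p = 4.12e-18, and adjusted p = 0.0240 with an estimated correlation). Milk protein genes were lower (9 of 16 called, median -1.26, adjusted p = 1.46e-13, and adjusted p = 0.0240 with an estimated correlation), with medians from -1.45 to -0.70 over leave-outs. So were myoepithelial markers (9 of 17 called, median -0.34, adjusted p = 0.0105, and adjusted p = 0.0244 with an estimated correlation), with Oxtr (-1.47), Lgr5 (-1.09), Myh11 (-0.85) and Krt14 (-0.79). Immediate early and dissociation stress genes were lower (15 of 25 called lower and 1 higher, median -0.72, adjusted p = 1.66e-06, and adjusted p = 0.125 with an estimated correlation). NF-kB targets were lower (12 of 20 called lower and 2 higher, median -0.55, adjusted p = 0.0106, and adjusted p = 0.288 with an estimated correlation) and lost the call without wild-type mouse 2 or its non-clonogenic array. The test called 4873 genes, 2718 higher and 2155 lower, 1604 of them by 2-fold or more. The count was 2639 and 2611 without knockout mouse 1 or 2, 3125 in knockout mice alone and 3137 at 1.5-fold or more.

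**Figure D4:**
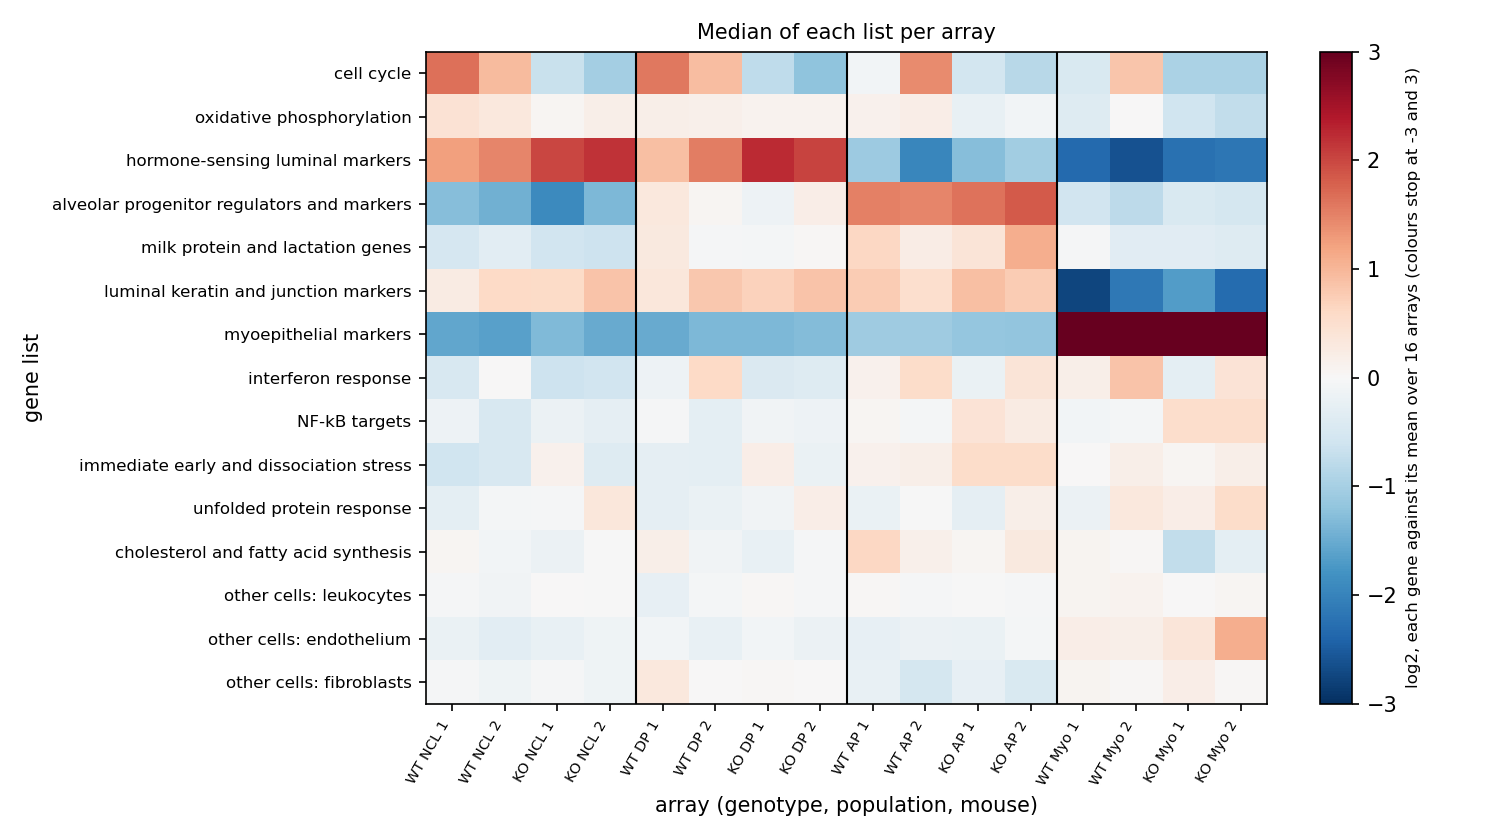
Median of 15 gene lists (vertical axis) in each of the 16 arrays (horizontal axis, grouped by population), as log2 difference of each gene from its mean over all arrays, from blue (lower) to red (higher), with colours ending at -3 and 3. Hormone-sensing markers are high in the non-clonogenic and ductal arrays, alveolar markers in the alveolar arrays and myoepithelial markers in the myoepithelial arrays, and the cell cycle list ranges from 1.65 in wild-type non-clonogenic mouse 1 to -1.21 in knockout ductal mouse 2.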

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

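The tests of a lone mouse, of other cell types, of the oestrous stage, of S-phase against mitotic genes and of splits that keep the mice, and every leave-out of a single array, were chosen after the result was seen, and the other tests before. Among the 77 groups of 4 within-mouse differences of named genes, 3 had a mouse far from the others, and chance alone gives about 1 in 20 groups, since the test uses a 95% critical value. Bik, myoepithelial minus luminal, was -4.65 in wild-type mouse 1 and between -4.54 and -4.51 in the other mice. Atp6v1b1, ductal minus alveolar, was -2.04 in wild-type mouse 1 and between -3.19 and -3.12 in the others. Cyp1b1, non-clonogenic luminal minus alveolar, was -7.35 in wild-type mouse 2 and between -6.49 and -6.37 in the others.

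The knockout effect differed between populations for 114 genes, of which 27 had their largest effect in non-clonogenic luminal cells, 35 in ductal, 22 in alveolar and 30 in myoepithelial cells. Of 66 genes named in the within-population comparisons or by the F test, 17 differed. Among them Lcn2 (adjusted p = 0.00209), Cd1d1 (0.00226), Clic6 (0.00474), Muc15 (0.00474) and Rspo1 (0.00526) have their effects above. C1qtnf1 had -2.48 in alveolar and -1.44 in ductal cells, and -0.06 and -0.03 in non-clonogenic and myoepithelial cells (adjusted p = 0.00744). In wild type C1qtnf1 read 6.32 in non-clonogenic, 8.00 in ductal and 10.13 in alveolar cells, and Nox4 read 5.96, 7.01 and 7.65. In ductal progenitors a shift of the wild-type arrays toward alveolar cells thus cannot be told apart from a knockout effect on these 2 genes. In myoepithelial cells Adamts18 had -1.73 (adjusted p = 0.00744), Gpx2 -1.76 (0.00899) and Olfm2 1.51 (0.0165), while their effects in the luminal populations lay between -0.10 and 0.23. Adamts18 read under the lower quartile of all probe sets in every luminal array, where a fall cannot be seen, so no different response is shown for it. Olfm2 did in alveolar cells and read near it in the others, and Gpx2 read 6.86 to 7.04 in luminal cells. Nox4 had 1.42 in myoepithelial cells against -1.74 in ductal progenitors (adjusted p = 0.0155), Glis3 had 1.38 against -0.79 (0.0198), and Maob had -1.78 in myoepithelial and 1.51 in alveolar cells (0.0198). Mal had 1.65 and 1.64 in non-clonogenic and ductal cells and -0.91 in alveolar cells (adjusted p = 0.0187), and Rhbdl2 had 1.80, 2.50 and -0.38 (0.0298). Foxi1, with 2.03 in alveolar progenitors (adjusted p = 0.0253), Arhgef6, with 1.81 (0.0271), and Kcne3, with 1.92 (0.0418), had effects between -0.75 and 0.38 elsewhere. Foxi1 and Kcne3 read under the lower quartile in all non-clonogenic and myoepithelial arrays and near it in ductal ones, where differences are compressed, and Maob did in non-clonogenic and ductal arrays. For them effects near 0 there do not show a different response.

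For ductal against alveolar progenitors, 1 of the 35 free splits of the 8 arrays, the real one, gave as many called genes in a fit of those arrays (2541, against at most 12). The same held for non-clonogenic luminal against alveolar cells (1 of 35, 4221 against at most 1). Free splits ignore that both populations come from the same mice, and splits with 1 array of each mouse on each side number 8, too few for a share under 0.05; the other 7 called 0 genes in each comparison (limma). For myoepithelial against luminal cells chance can be excluded, since 1 of 100 free splits (6025, against at most 1288) and 1 of 100 splits that take 1 array of each mouse (at most 1086 in the others) gave as many. For non-clonogenic luminal cells against ductal progenitors, 2 of 35 splits gave as many as the real 53, and chance cannot be excluded by this count. The other such split parted the genotypes and called 2486 genes. It keeps both arrays of a mouse on the same side, and the mice make only 3 such splits, so it draws no conclusion on the genotype. The 26 splits of other kinds called at most 2, and the 7 that part the arrays of each mouse called 0 (limma).

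The first pattern is the lower level of cell cycle genes in the knockout arrays. The 4 mice make 3 splits into pairs, too few for a share under 0.05: 1 of them, the real one, called 1748 genes and the other splits at most 4. Against 1 mouse alone as the source, the list's median averaged over populations was -1.59 or lower whichever mouse was left out, which speaks for the average only: without wild-type mouse 2 it was -0.70 in alveolar and -0.41 in myoepithelial cells, so that mouse is not excluded as the source of much of the fall there. Against other cell types in the wild-type sorts, the lowest knockout median of the leukocyte, endothelial and fibroblast lists was -0.0800. Against alleles linked to the deletion as the source of the calls, the share called among the 200 genes nearest to Cpeb2 was 1.23 times that of all others (Fisher's exact test, two-sided, p = 0.290), and 98.6% of calls lay outside them. The genotype labels do not give the strain of the deleted allele. This speaks for the calls as a whole and not for single neighbours such as Prom1. The stage of the oestrous cycle cannot be told apart from the genotype, since no label gives it and Pgr differed by 1.15 between the wild-type mice in non-clonogenic luminal cells (9.84 and 10.98, against 11.27 and 11.85 in knockout). Loss of Cpeb2 stays an open, untested explanation beside it.

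The second pattern is the number of called genes in ductal progenitors. To test alveolar-like cells in the wild-type ductal gate as the whole source, genes level between non-clonogenic luminal and alveolar cells were counted. They were called 3.69 times as often in ductal as in non-clonogenic cells (295 and 80 of 6160). Over all genes the ratio was 3.60 (1272 and 353 of 17097). The adjusted threshold admits larger p-values where more genes are called, which raises the share in any set. The ratio of 3.69 therefore cannot decide, and alveolar-like cells stay open as a source. The ductal array of wild-type mouse 1 may be the source of much of the count, which was 47 without it. Leaving out the ductal array of knockout mouse 1 gave 57, so the loss is not particular to that array, and leaving out that of wild-type mouse 2 gave 2945. Whether the knockout acts more widely in ductal progenitors stays open (its effect differed from that in non-clonogenic cells for 2 genes), and so does RNA integrity, untested here, since the 3′ control probes part the genotypes in these arrays.

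The third pattern is a gap between S-phase and mitotic genes in some arrays of wild-type mouse 1. S-phase minus mitotic median, each against the knockout mean, was 1.27 in its alveolar and 0.14 in its myoepithelial cells, but -0.32 in its non-clonogenic luminal cells and -0.22 in its ductal progenitors. The arrays of wild-type mouse 2 ran from -1.15 to -0.24 and those of knockout mice from -0.21 to 0.21. The knockout arrays are their own reference, so their values in a population mirror each other by construction and are no like measure for wild-type arrays. Fewer dividing cells with all phases alike cannot be told apart from a shift between phases, since the lower of the first values, 0.14, lies within the largest gap of the other 14 arrays (1.15). The lists, drawn up after the data were seen, have 29 measured genes each, of which 13 and 22 are also in the cell cycle list, and no biological explanation was tested.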

How the results depend on the processing

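The leave-outs of single arrays were chosen after the data were seen, as were the tests of lists in the mean effect and between populations with the parent block, with an estimated correlation and with a mouse left out. With 2 arrays per group, most knockout calls named for a single population were lost without some mouse, and leave-outs change both the estimates and the degrees of freedom. The parent block moved no count by more than 1.5-fold except those of genes in the mean effect and lists in alveolar progenitors, and ended the call of 1 list, the endothelial one of myoepithelial against luminal cells. Its other changes to lists were added calls, among them hypoxia and glycolysis in ductal progenitors and in the mean effect, and interferon response in alveolar progenitors.

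Genes called in the mean effect numbered 3431 with the parent block, 696 at 1.5-fold or more and 492 from the mean of each mouse's arrays. With array weights the counts were 847 in ductal, 389 in alveolar and 50 in myoepithelial cells, and without dim genes 102 in myoepithelial cells. From the 4 arrays of a population alone they were 86 in non-clonogenic luminal cells, 69 in ductal progenitors and 0 in myoepithelial cells (limma, 1550 genes at an unadjusted p under 0.05, smallest adjusted p = 0.400). At 1.5-fold or more, 4160 genes differed between myoepithelial and luminal cells, 2446 between ductal and alveolar progenitors and 3137 between non-clonogenic luminal cells and alveolar progenitors. Ductal against alveolar progenitors gave 2154 in wild-type mice, and in knockout mice non-clonogenic luminal cells gave 40 against ductal and 3125 against alveolar progenitors.

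Leaving out a mouse or an array, called genes ran from 0 (without knockout mouse 2) to 906 in non-clonogenic luminal cells, 17 to 3393 in ductal, 3 to 315 in alveolar and 13 to 1391 in myoepithelial cells. They ran from 279 to 2603 in the mean effect and from 1 to 1047 for effects that differ between populations. Between populations they ran from 5106 to 8513 for myoepithelial against luminal cells, 42 to 281 for non-clonogenic luminal against ductal, 1748 to 4256 for ductal against alveolar and 2611 to 5447 for non-clonogenic luminal against alveolar cells. The within-mouse correlation (from -0.0294 to 0.0713) and the spread shared by all arrays were estimated anew in each fit, so arrays of other populations could move counts too. Which of them did so was not tested.

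Gene lists called by cameraPR numbered 7 in non-clonogenic luminal, 5 in ductal, 5 in alveolar and 8 in myoepithelial cells and 9 in the mean effect, and with an estimated correlation 0 in each (camera, with 1, 1, 3, 4 and 2 lists at an unadjusted p under 0.05), while fry called 2, 3, 0, 5 and 8. The parent block gave 8 lists in alveolar cells. Between populations 8, 12, 8 and 6 lists were called, and 3, 4, 2 and 4 with an estimated correlation. Over leave-outs the lists ran from 3 to 7 in non-clonogenic luminal, 3 to 6 in ductal, 5 to 7 in alveolar and 7 to 11 in myoepithelial cells and 6 to 12 in the mean effect. Between populations they ran from 5 to 9, 6 to 13, 7 to 9 and 6 to 10.

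Of 24 called genes named in non-clonogenic luminal cells, 24 lost the call without at least 1 mouse. So did 40 of 40 in ductal, 21 of 21 in alveolar and 23 of 24 in myoepithelial cells (Adamts18 kept it). In the mean effect 38 of 48 did, and Ccna2, Ly6d, Mcm5, Papln, Pbk, Pclaf, Rspo1, Top2a, Trip13 and Zwilch kept it. Between populations 4 of 61, 9 of 21, 10 of 47 and 8 of 48 did. Of 390 values of named genes, 383 kept their label with the parent block, 387 with centring, 380 with a second quantile normalization and 359 with the mean of all probe sets. With that mean, Sdha changed sign in the mean knockout effect (0.0913) and between ductal and alveolar progenitors (-0.0201).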

Other observations

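The other members of the CPEB family were measured in the same arrays. None of Cpeb1, Cpeb3 and Cpeb4 was called in a knockout comparison on its brightest probe set, with mean effects of 0.16 ± 0.10, 0.09 ± 0.08 and 0.08 ± 0.20. The probe sets of Cpeb4 disagreed. One was higher in knockout by 0.75 ± 0.16 in the mean of the 4 populations (adjusted p = 0.0143 over all probe sets), with differences of 0.92, 0.63, 0.65 and 0.79 in non-clonogenic, ductal, alveolar and myoepithelial cells. The brightest differed by -0.42, -0.98, 1.08 and 0.65. The remaining probe set differed by 0.04, -0.59, 0.78 and 0.20 in the same order, with a mean effect of 0.10 ± 0.17. The probe set with 0.75 was singled out after its values were seen. Between populations, in the mean of both genotypes, Cpeb4 (-1.39 ± 0.22) and Cpeb2 (-1.49 ± 0.23) were lower and Cpeb1 (0.55 ± 0.11) higher in myoepithelial than in luminal cells. Cpeb2 read 5.41 and 6.03 in wild-type myoepithelial arrays. Cpeb1 read under the lower quartile of all probe sets in every luminal array. In myoepithelial arrays it read 4.85 and 4.41 in wild type and 5.43 and 5.03 in knockout. Only 5.43 lay above that quartile, so the difference of Cpeb1 is not exact. Epcam was higher in knockout by 0.24 ± 0.05 in the mean of the 4 populations (adjusted p = 0.00994), and its other probe set differed by 0.09 ± 0.11.

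A pair of hormone-responsive genes was read in each mouse. In non-clonogenic luminal cells Greb1, an estrogen-induced gene, read 5.14 in wild-type mouse 1 and 7.44 in wild-type mouse 2, and 7.99 and 6.60 in knockout mice 1 and 2. In ductal progenitors it read 4.86, 7.73, 8.51 and 7.39 in the same order, and Pgr read 9.84, 11.11, 11.61 and 11.89. In alveolar cells Greb1 read 4.80 and 4.90 in the wild-type mice, under the lower quartile of all probe sets, where a difference between mice cannot be seen. Pgr ran the other way there (7.12 and 6.63) and in myoepithelial cells (7.12 and 6.53). Both genes were chosen after the knockout effect was seen. The estrogen response list, fixed before, had levels of -0.12 and 0.03 in wild-type mice 1 and 2 in non-clonogenic luminal cells and -0.21 and 0.09 in ductal progenitors, and the difference between mice was not tested. Lists that passed in none of the comparisons were those of the Notch pathway (median 0.11 in the mean knockout effect, adjusted p = 0.320), ribosomal proteins (-0.04, adjusted p = 0.0937), adipocytes (0.09, adjusted p = 0.344), pericytes (0.07, adjusted p = 0.506) and red cells (-0.14, adjusted p = 0.320). The differences between probes near the end and the middle of Gapdh, a hint of RNA integrity, ran from 0.02 to 0.60 in wild-type and from -0.03 to 0.49 in knockout arrays. In alveolar progenitors it was lower in wild-type (0.14 and 0.18) than in knockout arrays (0.49 and 0.23), opposite to ductal progenitors.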
